A study of Mus musculus with 14 samples.

How the data were processed

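Poly(A) RNA libraries were prepared with a TruSeq kit and sequenced in pairs on an Illumina instrument, per the labels. The samples are 3 control and 3 sgADAR1 libraries of FC1199 cells under interferon gamma and 4 control and 4 sgADAR1 libraries of pancreatic cancer tissue. Per the submitters' processing notes, reads were aligned to GRCm39 with HISAT2, counted per gene with featureCounts, and compared with DESeq2. The versions of those tools, the annotation release and the strand setting are not given in the sources used here. The deposited tables, 1 for cells and 1 for tumours, hold whole-number read counts per gene and FPKM per gene made by the authors, with exonic sizes and gene positions, for 56691 genes each. No count column and no FPKM column was left unused (0). FPKM recomputed from the deposited counts, library totals and exonic sizes was within 0.0051 of the deposited FPKM for 100% of values in both tables. Of the 56691 gene identifiers, 98.8% were in GENCODE mouse release M39, and 100% of those overlapped the position given there. A double knockout of ADAR1 and STAT1 that the design text mentions was not analysed here.

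Groups, comparisons, tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The plan was a limma fit on FPKM unless read counts were found. Counts were found, so the main test was edgeR 4.0.16 (R 4.3.3) on the counts, with the limma fit kept as an alternative. Each table was fitted on its own with TMM scaling, the default low-count filter of edgeR, a robust quasi-likelihood fit and a two-sided test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the same fit, as the absolute log2 fold change over the root of the F statistic. The 95% intervals were built from them. The mean level of a gene in the text is the deposited FPKM. FPKM is scaled by library totals and the fold changes by TMM as well, so ratios of mean FPKM differ from the fold changes. In the cells the TMM factors were 1.06 in the control libraries and 0.935 to 0.950 in the sgADAR1 libraries. Fitted log2 fold changes in the cells therefore lie above those of the mean FPKM. For Adar, an exact two-sided permutation test of the group means was added. Genes with 1 to 3 counts in a group are given with a count ratio and a 95% counting interval, and genes with 0 counts with a bound at a floor of 3 counts over the group. The depth of 13535358 to 18252022 counts per library sets the counting error, and intervals and floors cover counting error only.

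For gene lists, 46 lists of pathways and cell type markers were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, for lists with at least 3 tested members. Lists were adjusted by Benjamini-Hochberg within a comparison. Camera with an estimated correlation and fry were alternatives. The estimated correlation was 0.279 for interferon-stimulated genes in the cells and 0.552 for interferon-gamma-responsive genes in the tumours. Where it exceeds the preset value, the p-values at that value can be far too small. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. The adjusted p over the list alone is a Benjamini-Hochberg adjustment over its tested members. Named genes were set by rule: a set named whatever its values (Adar and genes of interferon signalling, with dendritic and T cell genes in tumours), the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap with a mean FPKM of at least 1 in a group, and up to 3 members with the smallest p in each list described in detail. Shared calls were counted among genes tested in both comparisons and tested with Fisher's exact test. The difference between the 2 log2 fold changes of a gene was divided by the root of the summed squared standard errors and adjusted by Benjamini-Hochberg. Gene ontology terms of 15 to 500 genes were tested by the hypergeometric distribution for genes changed at least 2-fold, against tested genes with any term.

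Alternatives were DESeq2 1.42.0, DESeq2-type size factors in edgeR, no low-count filter, a mean FPKM of at least 5, an absolute log2 fold change of at least 1, replicate number as a block, and limma on log2(FPKM + 1) with a pseudocount of 0.1, no filter, median-ratio rescaling, quantile normalization, TPM or array weights. Each library was also left out in turn. Whether replicate numbers pair the libraries was checked by correlating deviations from the group mean across genes. In the cells the same numbers correlated at 0.46, 0.24 and 0.29, and control 2 with sgADAR1 3 at 0.31. Replicate 1 of either group correlated at -0.42 to -0.23 with replicates 2 and 3 of the other. Between cell libraries chi-square per degree of freedom was 24.6 and 26.3 for control pairs with replicate 1 and 3.15 for 2 and 3. In the sgADAR1 group it was 7.53 and 7.67 against 2.65. Replicate 1 thus stood apart in both groups, which the main fit did not model. The pipeline was tested on simulated data made from the same tables. For cells it recovered 86.5% of 2-fold and 97.9% of 4-fold changes with 6.60% of calls false. For tumours it recovered 38.5% and 86.5%, with 6.11% false. The test of the difference recovered 82.8% at log2 2 and 100% at log2 4, with 7.23% false. The simulation drew each gene independently, changed 200 genes and held no structure among replicates. In the real cells 36.1% of tested genes passed and replicate 1 stood apart, so the simulated rates need not hold for these data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.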

Results

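Poly(A) RNA was sequenced from 14 mouse libraries in 4 groups. FC1199, a mouse pancreatic cancer cell line, gave 3 libraries labelled sgControl and 3 labelled sgADAR1, all from cells kept with interferon gamma at 10 ng per ml for 24 hours. No library from untreated cells was analysed here. Tissue labelled pancreatic cancer gave 4 libraries labelled sgControl and 4 labelled sgADAR1. The cell libraries held 15314665, 15233942 and 16564904 counts in the control group and 13744950, 14148322 and 16565654 in the sgADAR1 group, replicates 1 to 3. The tumour libraries held 16165353, 15375593, 13535358 and 15596656 counts in the control group and 18252022, 14659602, 15275058 and 17013806 in the sgADAR1 group, replicates 1 to 4. Levels are given as mean FPKM ± SD over the libraries of a group (n = 3 for cells, n = 4 for tumours). Fold changes are log2 of sgADAR1 over control from the TMM-scaled fit, not ratios of mean FPKM. The labels do not say whether replicates are separate cultures or animals, so the p-values measure only the spread between these samples.

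The targeted gene, Adar (ENSMUSG00000027951, GRCm39 chromosome 3, 89622329 to 89660753), encodes an enzyme that edits adenosine to inosine in double-stranded RNA. In the cells its FPKM was 10.67, 14.39 and 14.29 in the control libraries and 31.37, 32.89 and 32.35 in the libraries labelled sgADAR1. The mean was 13.1 ± 2.12 against 32.2 ± 0.771, higher in 3 of 3 libraries. The TMM-scaled log2 fold change was 1.47 (SE 0.12, 95% interval 1.20 to 1.73, edgeR adjusted p = 1.16e-05). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries can give. In the tumours Adar FPKM was 3.12, 4.15, 4.69 and 6.65 in the control libraries and 4.99, 7.84, 7.45 and 7.38 in the libraries labelled sgADAR1. The tumour log2 fold change of 0.48 (SE 0.20, 95% interval 0.04 to 0.93) did not pass (edgeR adjusted p = 0.295). The exact two-sided permutation p was 0.0571, where 0.0286 is the smallest possible. The Adar transcript was therefore not lower in either set, which goes against a simple reading of the labels. Gene-level counts do not check an edit made by a guide, which can leave the transcript in place.

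**Figure D1:**
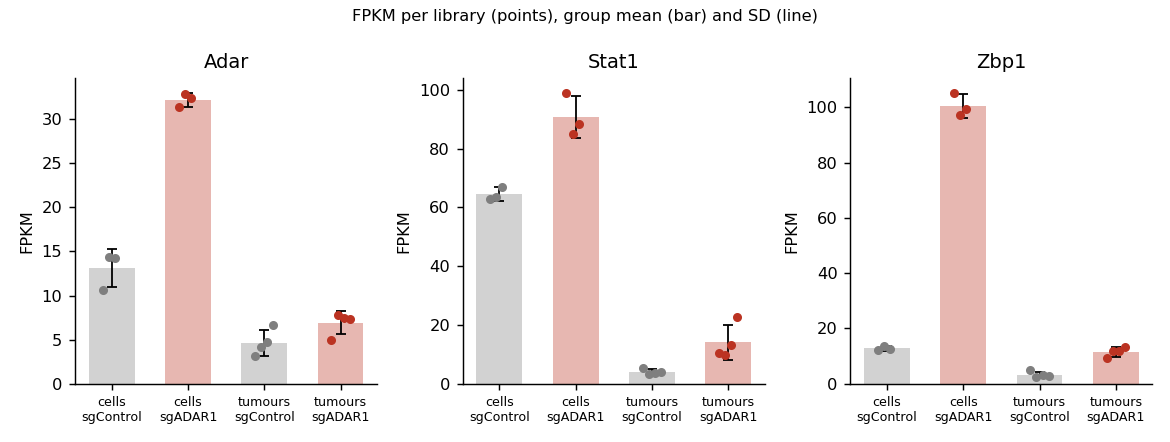
Levels of Adar, Stat1 and Zbp1 in FPKM (vertical axis, from 0) in the 4 groups; points are libraries, bars group means and lines SD (n = 3 for cells, n = 4 for tumours). Mean Adar was 13.1 and 32.2 FPKM in the cells and 4.65 and 6.92 FPKM in the tumours.

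The cell comparison asks how FC1199 cells under interferon gamma differ when they carry the ADAR1 guide. Genes of the antiviral interferon response were higher in the libraries labelled sgADAR1. Isg15, a ubiquitin-like protein made in response to interferon, went from 13.6 ± 1.52 to 357 ± 57.7 FPKM (log2 4.88, SE 0.15, edgeR adjusted p = 9.02e-09). Cxcl10, which attracts T cells, went from 19.97 ± 3.05 to 502 ± 53.2 FPKM (log2 4.82). Among the genes that were lower were Aebp1, from 6.54 ± 0.755 to 0.0767 ± 0.0513 FPKM (log2 -6.19), and Ddr2, a collagen receptor, from 4.05 ± 0.658 to 0.04 FPKM (log2 -6.50). Most cell cycle genes were lower, by smaller amounts.

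All 33 measured interferon-stimulated genes rose, and 33 rose when adjusted over the list alone (median log2 4.17, camera adjusted p = 3.02e-227, 0.00857 with an estimated correlation). Ifit3 went from 2.55 ± 0.217 to 630 ± 59.7 FPKM, Ifit1 from 1.57 ± 0.115 to 364 ± 42.2 FPKM and Mx2 from 0.673 ± 0.114 to 79.5 ± 4.25 FPKM. All 23 measured interferon-gamma-responsive genes rose, and 23 adjusted over the list alone (median 1.49, camera adjusted p = 1.55e-34, 0.0435 with an estimated correlation). Their examples were Gbp2, a guanylate-binding protein, from 839 ± 27.2 to 3189 ± 264 FPKM, Gbp3 from 153 ± 1.82 to 511 ± 35.5 FPKM, and Ido1, which breaks down tryptophan, from 11.2 ± 0.888 to 45.3 ± 2.63 FPKM. Among 23 genes of double-stranded RNA sensing, 15 rose and 0 fell, and 17 and 0 adjusted over the list alone (median 2.15, camera adjusted p = 1.71e-50, 0.0187 with an estimated correlation). Ifih1, a sensor of long double-stranded RNA, went from 5.23 ± 0.189 to 34.6 ± 1.22 FPKM, and Eif2ak2, a kinase that double-stranded RNA activates, from 18.9 ± 2.76 to 75.7 ± 5.68 FPKM. Oas3 went from 2.77 ± 0.235 to 30.2 ± 1.08 FPKM, Dhx58 from 2.87 ± 0.337 to 38.1 ± 1.76 FPKM and Oas2 from 1.27 ± 0.203 to 26.4 ± 1.69 FPKM. Zbp1, a sensor of left-handed nucleic acid, went from 12.8 ± 0.766 to 101 ± 4.20 FPKM. In the cytosolic DNA sensing list 8 genes rose and 1 fell of 11 (9 and 1 adjusted over the list alone, median 2.07, camera adjusted p = 1.46e-27, 0.0234 with an estimated correlation).

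MHC class I antigen presentation held 15 genes that rose and 1 that fell of 20 (16 and 2 adjusted over the list alone, median 0.88). Its call (camera adjusted p = 2.15e-09) was lost at an adjusted p = 0.217 with an estimated correlation. H2-T23 went from 38.1 ± 3.60 to 105 ± 14.2 FPKM, the peptide transporter Tap1 from 61.1 ± 3.96 to 117 ± 3.52 FPKM, the transactivator Nlrc5 from 6.09 ± 1.08 to 16.8 ± 0.864 FPKM and H2-K1 from 272 ± 12.7 to 406 ± 43.3 FPKM. Of 7 T cell-attracting chemokines, 5 rose and 0 fell, as they did adjusted over the list alone (5 and 0; median 3.30, camera adjusted p = 1.07e-20, 0.0209 with an estimated correlation). Cxcl11 went from 4.51 ± 0.786 to 105 ± 5.35 FPKM, Cxcl9 from 13.2 ± 0.721 to 78.1 ± 6.18 FPKM and Ccl5 from 2.12 ± 0.470 to 18.7 ± 2.76 FPKM. Cd274, the ligand of the checkpoint receptor Pdcd1, went from 16.8 ± 3.59 to 98.0 ± 0.700 FPKM (log2 2.71), and Stat1, a transcription factor of interferon signalling, from 64.5 ± 2.22 to 90.7 ± 7.28 FPKM (log2 0.66).

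In the integrated stress response list 20 genes rose and 0 fell of 24 (20 and 0 adjusted over the list alone, median 0.73, camera adjusted p = 8.56e-06; adjusted p = 0.419 with an estimated correlation). Cth went from 9.90 ± 1.70 to 23.01 ± 3.80 FPKM, Atf3 from 24.3 ± 7.11 to 59.4 ± 2.27 FPKM and Asns, asparagine synthetase, from 67.2 ± 17.8 to 145 ± 7.62 FPKM. Of 29 cell cycle genes, 1 rose and 21 fell (2 and 23 adjusted over the list alone, median -0.46, camera adjusted p = 5.56e-05; adjusted p = 0.419 with an estimated correlation). The DNA helicase subunit Mcm3 went from 43.2 ± 8.24 to 18.3 ± 2.03 FPKM, the mitotic kinesin Kif20a from 26.6 ± 2.95 to 13.7 ± 0.983 FPKM and the topoisomerase Top2a from 117 ± 2.91 to 64.0 ± 7.09 FPKM. Of 9 fibroblast markers, 2 rose and 5 fell (2 and 6 adjusted over the list alone, median -1.53, camera adjusted p = 8.82e-06, 0.0435 with an estimated correlation). The limma fits on FPKM did not call this list, at adjusted p from 0.0871 to 0.288. Pdgfra, a growth factor receptor, went from 2.11 ± 0.0781 to 0.030 ± 0.010 FPKM and the collagen gene Col1a1 from 1.39 ± 0.0666 to 0.303 ± 0.0611 FPKM.

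The largest changes were ranked among genes that passed, with groups that did not overlap and a mean of at least 1 FPKM in a group. Gm and Rik models, pseudogenes and immunoglobulin or T cell receptor segments were left out. The 8 largest rises by fitted fold were Rsad2, Trim30c, Ifit3b, Ifit3, Ifit1, Ifnb1, Mx1 and Cmpk2. Rsad2, an antiviral enzyme (ENSMUSG00000020641, chromosome 12, 26492745 to 26506451), went from 0.147 ± 0.0850 to 134 ± 13.0 FPKM (log2 9.98, SE 0.23, edgeR adjusted p = 1.96e-09). Ifit3 (ENSMUSG00000074896, chromosome 19, 34560931 to 34566131) had a log2 fold change of 8.12 (SE 0.13). Ifnb1, interferon beta (ENSMUSG00000048806, chromosome 4, 88440262 to 88441011), had 1 count over the control libraries and 265 over the sgADAR1 libraries, a ratio of 316 with a 95% counting interval of 56.2 to 12532. Trim30c had 2 counts against 1638, a ratio of 977 (270 to 8074). Ifit3b went from 0.493 ± 0.255 to 155 ± 13.1 FPKM, Mx1 from 0.477 ± 0.163 to 67.7 ± 4.61 FPKM and Cmpk2 from 0.447 ± 0.0751 to 58.4 ± 5.47 FPKM. The 8 largest falls were Thbs2, Fgfr1, Col3a1, Rnf144b, Pcdh18, Ddr2, Aebp1 and Inha. Fgfr1, a growth factor receptor (ENSMUSG00000031565, chromosome 8, 26003670 to 26065734), had 1497 counts over the control libraries and 1 over the sgADAR1 libraries, a ratio of 1255 (225 to 49601). Thbs2, a matrix glycoprotein, had 448 counts against 0, at least 125-fold lower with a floor of 3 counts over the group. Col3a1, a fibrillar collagen, had 833 counts against 2, a ratio of 349 (96.4 to 2888). The counts were 486 against 2 for Rnf144b (ratio 204, 56.1 to 1687), 382 against 2 for Pcdh18 (ratio 160, 44.0 to 1327) and 107 against 1 for Inha (ratio 89.7, 15.8 to 3576). Intervals and floors cover counting error only. Members of the Ifit, Mx, Gbp, Trim30, Tgtp and H2 families share sequence, and how reads shared between them were counted is not given in the sources used here.

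JAK-STAT and interferon receptors held 10 higher and 1 lower of 16 (11 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 3.02e-06, lost at adjusted p = 0.177 with an estimated correlation). MHC class II antigen presentation held 5 higher and 0 lower of 7 (6 and 0 adjusted over the list alone, median 0.81), a call (camera adjusted p = 0.0224) that was lost with an estimated correlation (adjusted p = 0.177) and without control replicate 1 (0.0615, the highest of 6 such fits). Immune checkpoint genes held 6 higher and 1 lower of 8 (6 and 1 adjusted over the list alone, median 0.78, camera adjusted p = 2.40e-05, 0.0435 with an estimated correlation). Of 16 p53 target genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 0.0131, lost at adjusted p = 0.257 with an estimated correlation). Of 13 mitochondrially encoded genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone, median -0.35, camera adjusted p = 0.0212, lost at adjusted p = 0.419 with an estimated correlation). Their share of counts was 2.69, 2.67 and 2.42% in the control libraries and 2.16, 2.02 and 2.12% in the sgADAR1 libraries. Immediate early and heat shock genes held 6 higher and 0 lower of 15, also when adjusted over the list alone (6 and 0), with a median of 0.07 that took the other sign (-0.01) under another scaling. Their call (camera adjusted p = 0.0281) was lost with an estimated correlation (adjusted p = 0.217) and without control replicate 2 (0.0514). Mature dendritic cell markers held 4 higher and 2 lower of 6 (4 and 2 adjusted over the list alone, median 0.83), called by camera (adjusted p = 0.0212) but not with an estimated correlation (adjusted p = 0.177) or without control replicate 1 (0.0513). Type 1 conventional dendritic cell markers held 1 higher and 1 lower of 4 (2 and 1 adjusted over the list alone), with a median of 0.14 that was -0.03 under another scaling. Their call (camera adjusted p = 0.0118; adjusted p = 0.257 with an estimated correlation) was lost without control replicate 2 (0.0592) or sgADAR1 replicate 1, 2 or 3 (0.127, 0.0955 and 0.0917).

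The lists of editing enzymes, of type I and III interferon genes and of acinar and islet markers had fewer than 3 tested genes in both comparisons, and 11 lists of other host cells had fewer than 3 in the cells. The following lists did not pass in the cells by camera. MYC and ribosome biogenesis genes held 6 higher and 1 lower of 16 (7 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.122), and passed without control replicate 1 (0.0325) and, with all libraries, with no filter (0.0276), DESeq2 (0.0234) and limma array weights (0.0402). Hypoxia and glycolysis genes held 9 higher and 2 lower of 17 (9 and 3 adjusted over the list alone, median 0.28, camera adjusted p = 0.0978), and passed without control replicate 3 (0.0447) and, with all libraries, with no filter (0.0202), DESeq2 (0.0176) and fry (0.00327). Cholesterol synthesis genes held 0 higher and 2 lower of 15 (0 and 1 adjusted over the list alone, median -0.40, camera adjusted p = 0.288), and passed without control replicate 3 (0.0338). Epithelial and ductal markers held 3 higher and 2 lower of 13 (3 and 2 adjusted over the list alone), with a median of -0.05 where camera pointed up (adjusted p = 0.907). T cell markers held 1 higher and 2 lower of 5 (1 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.819). Regulatory T cell and exhaustion markers held 1 higher and 2 lower of 5 (1 and 2 adjusted over the list alone), with a median of 0.03 that was -0.13 under another scaling, a mean of -0.39 and a camera direction down (adjusted p = 0.594). Macrophage markers held 0 higher and 1 lower of 5 (0 and 0 adjusted over the list alone, median -0.30, camera adjusted p = 0.342; fry 0.0326), and replication-dependent histone genes 0 higher and 1 lower of 5 (0 and 1 adjusted over the list alone, median -0.59, camera adjusted p = 0.342). Endothelial markers held 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 0.188), and passed without control replicate 1 (0.0374) and with fry (0.0450).

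Of 14362 genes tested in the cells, 5180 (36.1%) passed, 2632 higher and 2548 lower, and 1374 of these changed at least 2-fold (559 higher, 815 lower; edgeR, Benjamini-Hochberg). Groups did not overlap for 50.5% of tested genes, where chance gives 10%. Across lists, camera called 21 of 31, 18 higher and 3 lower, and 7 with an estimated correlation. Other splits of the same libraries, which still hold part of the real difference, called up to 18 lists at the preset correlation. The split between higher and lower depended on the scaling. With limma on FPKM, which put the median log2 fold change of all genes at -0.13 against -0.02 here, 1472 genes were higher and 3473 lower. With a pseudocount of 0.1 that median was -0.15, and with array weights -0.13. All 56 named genes that passed kept their calls in each of the 6 fits that left out 1 library. Apart from the set named whatever its values, they were chosen from these same data for a large fold or a small p. Their calls therefore do not speak for the others. Of the 5180 calls, 3559 were kept without sgADAR1 replicate 3, the fewest, and 4967 without control replicate 1, the most.

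The tumour comparison asks what differs in whole tumours when the cancer cells carry the ADAR1 guide, and the series title names type 1 conventional dendritic cells as the host cells of interest. Genes of antigen presentation, interferon gamma response and T cells were higher in the libraries labelled sgADAR1. Cxcl9, which attracts T cells (ENSMUSG00000029417, chromosome 5, 92469206 to 92475938), went from 5.23 ± 2.00 to 84.9 ± 42.5 FPKM (log2 3.88, SE 0.40, edgeR adjusted p = 0.00210), higher in 4 of 4 libraries. H2-Eb1, a class II chain (ENSMUSG00000060586, chromosome 17, 34524841 to 34535648), went from 33.3 ± 6.65 to 171 ± 44.9 FPKM (log2 2.25, SE 0.22, edgeR adjusted p = 0.00184). Cd3g, a chain of the T cell receptor complex (ENSMUSG00000002033, chromosome 9, 44880870 to 44891729), went from 0.425 ± 0.186 to 3.46 ± 0.577 FPKM (log2 2.90).

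Of 25 interferon-gamma-responsive genes, 17 rose and 0 fell (22 and 0 adjusted over the list alone, median 2.20, camera adjusted p = 2.80e-46, 0.0308 with an estimated correlation). Ciita, the class II transactivator, went from 0.530 ± 0.243 to 3.27 ± 0.988 FPKM, Gbp8 from 2.93 ± 0.641 to 10.8 ± 2.60 FPKM and Tgtp2 from 1.84 ± 0.569 to 19.9 ± 10.98 FPKM. Of 33 interferon-stimulated genes, 12 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.78, camera adjusted p = 4.99e-23; adjusted p = 0.0517 with an estimated correlation). Sp100 went from 1.51 ± 0.686 to 6.48 ± 0.819 FPKM, Cmpk2 from 0.807 ± 0.249 to 2.54 ± 0.439 FPKM and Ifit1bl1 from 0.645 ± 0.217 to 2.42 ± 0.265 FPKM. Double-stranded RNA sensing held 5 higher and 0 lower of 23 (8 and 0 adjusted over the list alone, median 0.37, camera adjusted p = 8.39e-07, 0.0365 with an estimated correlation). Zbp1 went from 3.29 ± 1.03 to 11.5 ± 1.78 FPKM (edgeR adjusted p = 0.00489), Oas1a from 3.76 ± 1.23 to 10.0 ± 1.37 FPKM and Tlr3 from 6.95 ± 0.892 to 11.6 ± 0.938 FPKM (edgeR adjusted p = 0.0276). Stat1 went from 4.11 ± 0.924 to 14.04 ± 6.01 FPKM (log2 1.67, SE 0.28, edgeR adjusted p = 0.0125). The log2 fold change was 0.37 for Ifih1 (edgeR adjusted p = 0.282), 0.61 for Isg15 (0.513) and 0.14 for Eif2ak2 (0.922), none of which passed. Cytosolic DNA sensing held 6 higher and 0 lower of 11 (9 and 0 adjusted over the list alone, median 0.69, camera adjusted p = 4.97e-11, 0.0176 with an estimated correlation). Tlr3 did not pass in edgeR without control replicate 2, 3 or 4 (adjusted p = 0.0789, 0.0991 and 0.0544) or sgADAR1 replicate 2, 3 or 4 (0.0605, 0.0674 and 0.0969).

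Of 12 genes of MHC class II antigen presentation, 10 rose and 0 fell (12 and 0 adjusted over the list alone, median 2.30, camera adjusted p = 3.93e-46, 0.000312 with an estimated correlation). H2-Aa went from 31.7 ± 7.41 to 175 ± 49.5 FPKM and H2-DMb2 from 1.80 ± 0.400 to 10.5 ± 2.04 FPKM. MHC class I antigen presentation held 13 higher and 0 lower of 21 (17 and 0 adjusted over the list alone, median 1.26, camera adjusted p = 3.04e-33, 0.0308 with an estimated correlation). Tap1 went from 3.96 ± 0.737 to 20.5 ± 8.88 FPKM, Tap2 from 3.33 ± 0.855 to 11.3 ± 2.09 FPKM, the immunoproteasome subunit Psmb8 from 5.83 ± 2.35 to 27.1 ± 4.56 FPKM and H2-K1 from 110 ± 42.6 to 466 ± 151 FPKM. Of 10 T cell-attracting chemokines, 5 rose and 1 fell (5 and 2 adjusted over the list alone, median 1.18, camera adjusted p = 0.000112; adjusted p = 0.0517 with an estimated correlation). Over the limma fits on FPKM the camera adjusted p of this list ran from 0.000941 to 0.0705, so not every fit called it. Ccl5 went from 2.77 ± 0.835 to 10.3 ± 1.87 FPKM, Xcl1, which attracts cells with the Xcr1 receptor, from 0.385 ± 0.134 to 5.87 ± 5.26 FPKM and Cxcl10 from 4.44 ± 2.49 to 23.6 ± 15.2 FPKM (edgeR adjusted p = 0.0313). Cxcl10 did not pass in edgeR without control replicate 2, 3 or 4 (adjusted p = 0.0971, 0.101 and 0.0649) or sgADAR1 replicate 3 or 4 (0.0709 and 0.0824). H2-K1 did not pass without control replicate 3 (0.0521), nor Xcl1 without control replicate 2 (0.0523).

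Of 13 type 1 conventional dendritic cell markers, 5 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.70, camera adjusted p = 6.04e-09, 0.0139 with an estimated correlation). The list shares Tlr3 with double-stranded RNA sensing and Irf8 with the interferon-gamma-responsive genes. Tlr3 also had a log2 fold change of 2.76 in the cell line, so this call need not come from dendritic cells alone. The chemokine receptor Xcr1 (ENSMUSG00000060509, chromosome 9, 123681380 to 123691094) went from 0.10 ± 0.0876 to 0.667 ± 0.177 FPKM (log2 2.63, SE 0.50, edgeR adjusted p = 0.0210). Clec9a, a receptor for dead-cell actin (ENSMUSG00000046080, chromosome 6, 129385825 to 129401726), went from 0.360 ± 0.228 to 1.40 ± 0.299 FPKM (log2 1.90, SE 0.38, edgeR adjusted p = 0.0264). Batf3, a transcription factor of this lineage, had 1.32 ± 0.274 and 1.48 ± 0.707 FPKM (log2 0.08, edgeR adjusted p = 0.971). Of 18 T cell markers, 11 rose and 0 fell (16 and 0 adjusted over the list alone, median 2.02, camera adjusted p = 5.28e-23, 0.0176 with an estimated correlation). Itk went from 0.102 ± 0.0419 to 0.745 ± 0.333 FPKM and Cd2 from 0.562 ± 0.168 to 2.48 ± 0.552 FPKM. Of 14 CD8 T cell and cytotoxicity markers, 8 rose and 0 fell (13 and 0 adjusted over the list alone, median 2.25, camera adjusted p = 7.61e-21, 0.0176 with an estimated correlation). Fasl had 2 counts over the control libraries and 121 over the sgADAR1 libraries, a ratio of 52.6 (14.3 to 439). Ifng, interferon gamma itself, went from 0.105 ± 0.064 to 1.08 ± 0.465 FPKM (edgeR adjusted p = 0.0177), Cd8a from 0.443 ± 0.473 to 4.39 ± 0.901 FPKM (0.0292) and Gzmb from 0.868 ± 0.283 to 4.46 ± 2.86 FPKM (0.0299). Natural killer cell markers held 3 higher and 0 lower of 8 (6 and 1 adjusted over the list alone, median 2.17, camera adjusted p = 1.66e-06, lost at adjusted p = 0.0881 with an estimated correlation). These were Il2rb, from 0.422 ± 0.271 to 2.87 ± 0.970 FPKM, Klrd1, from 0.797 ± 0.594 to 5.86 ± 2.71 FPKM, and Gzma, from 0.555 ± 0.351 to 3.07 ± 1.58 FPKM. The natural killer list shares Gzma and Prf1 with the CD8 T cell and cytotoxicity list, and its lowest member had a log2 fold change of -2.14. Its call need not come from natural killer cells alone. Over the limma fits on FPKM the camera adjusted p of the natural killer list ran from 8.81e-06 to 0.0716, so not every fit called it. The mean level of B cell markers was 4.69 log2 CPM in sgADAR1 replicate 3 and 0.55 to 2.05 in the other 7 tumour libraries.

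Several of these genes did not pass by edgeR adjusted p in some fits that left out 1 tumour library, while their log2 fold changes stayed from 2.39 to 3.17 for Xcr1, 1.71 to 2.32 for Clec9a, 2.79 to 4.15 for Cd8a, 1.80 to 2.52 for Gzmb, 2.88 to 3.53 for Ifng, 2.42 to 3.36 for Klrd1 and 2.08 to 2.79 for Gzma. Xcr1 did not pass without control replicate 2 or 3 (0.0590 and 0.0563) or sgADAR1 replicate 2 or 4 (0.0569 and 0.0738). Clec9a did not pass without control replicate 2 or 3 (0.0701 and 0.0822) or sgADAR1 replicate 2 or 4 (0.0714 and 0.0782). Cd8a did not pass without control replicate 2 (0.0865) or sgADAR1 replicate 1, 2, 3 or 4 (0.0594, 0.0600, 0.0570 and 0.0914). Gzmb did not pass without control replicate 2 or 3 (0.0915 and 0.0911) or sgADAR1 replicate 3 or 4 (0.0722 and 0.0875), nor Ifng without sgADAR1 replicate 4 (0.0685). Klrd1 did not pass without control replicate 2 or 3 (0.0752 and 0.0703) or sgADAR1 replicate 3 or 4 (0.0606 and 0.0846). With 1 library left out Gzma passed only without control replicate 1 or sgADAR1 replicate 2, with an adjusted p from 0.0612 to 0.145 otherwise.

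**Figure D2:**
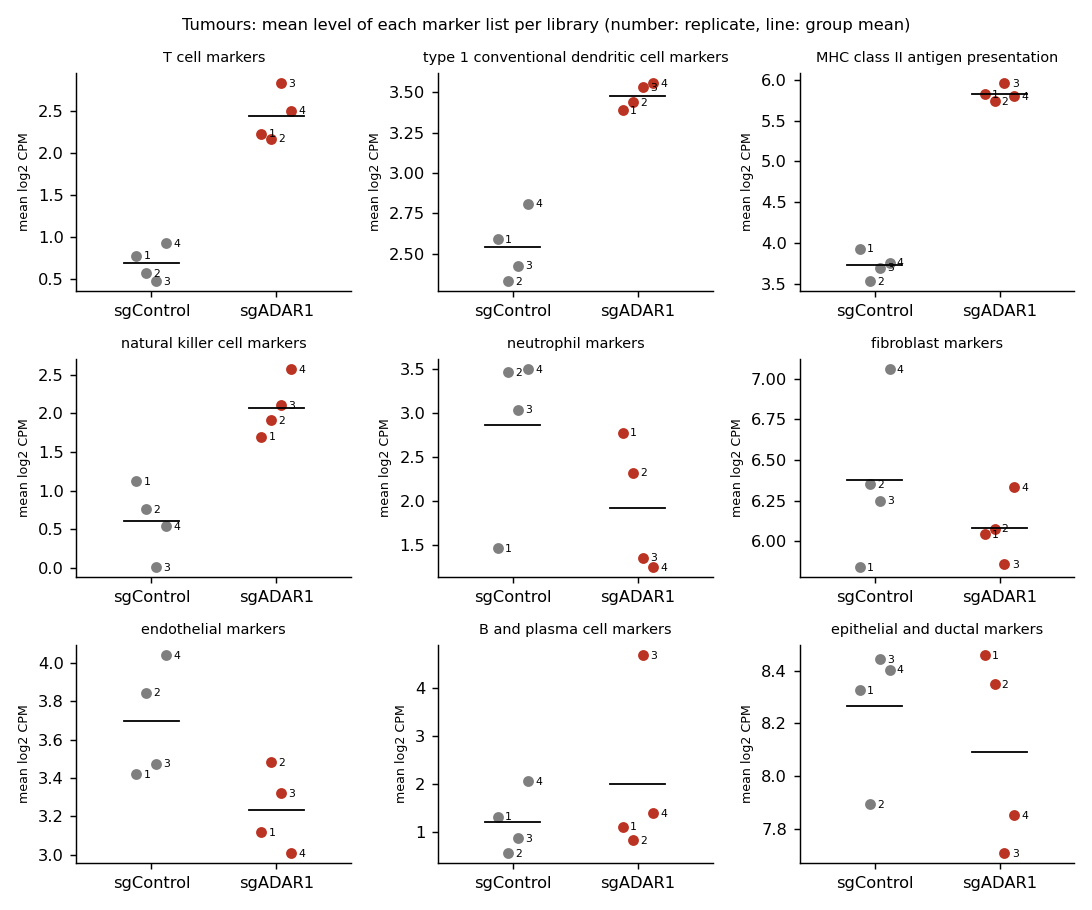
Mean level of 9 marker lists in each tumour library, in log2 CPM (vertical axis, which does not start at 0); points are libraries numbered by replicate and lines are group means (n = 4 per group). T cell, dendritic cell and MHC class II levels of the 4 sgADAR1 libraries all lie above those of the 4 control libraries, and the B cell level of sgADAR1 replicate 3 was 4.69.

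Of 13 neutrophil markers, 0 rose and 2 fell (1 and 5 adjusted over the list alone, median -1.02, camera adjusted p = 0.000723, lost at adjusted p = 0.392 with an estimated correlation). The 2 were Mmp8, a collagenase, from 1.27 ± 0.977 to 0.242 ± 0.0419 FPKM, and Hdc, histidine decarboxylase, from 1.66 ± 1.42 to 0.285 ± 0.115 FPKM, whose groups overlapped. Each passed in edgeR only with all libraries or without control replicate 1, with an adjusted p from 0.0744 to 0.118 for Mmp8 and from 0.0760 to 0.144 for Hdc otherwise. Ly6g, another neutrophil marker, had 0.385 ± 0.301 and 1.91 ± 0.311 FPKM (log2 2.14, edgeR adjusted p = 0.0609), and passed without control replicate 2 (0.0211). Of 14 endothelial markers, 0 rose and 1 fell, as they did adjusted over the list alone (0 and 1; median -0.52, camera adjusted p = 0.000186, lost at adjusted p = 0.322 with an estimated correlation). Fibroblast markers held 2 higher and 1 lower of 16 (2 and 2 adjusted over the list alone, median -0.51) and did not pass in the fit reported here (camera adjusted p = 0.111). They passed without control replicate 1 or 3 (0.000628 and 0.0273) or sgADAR1 replicate 4 (0.0389) and, with all libraries, with no filter (0.0156), a block by replicate number (0.0374), DESeq2 (0.0219), limma with no filter (0.0437) and TPM (0.0393). The 2 that rose are made by other cells as well: C3, a complement component, from 101 ± 20.5 to 270 ± 52.5 FPKM, and Ly6c1, a surface antigen, from 12.8 ± 4.20 to 59.6 ± 40.3 FPKM. Dcn, a matrix proteoglycan, went from 14.7 ± 7.74 to 5.66 ± 1.83 FPKM. With 1 library left out Ly6c1 passed only without sgADAR1 replicate 1 or 2 (0.0642 to 0.108 otherwise), and Dcn only without control replicate 1 (0.0641 to 0.115 otherwise).

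Among tumour genes chosen by the same rule as in the cells, the 8 largest rises by fitted fold were Gbp2b, Apol6, Alpi, Cxcl9, Ubd, Ceacam18, Xcl1 and H2-Eb2. Apol6, an apolipoprotein L family member, went from 0.0975 ± 0.0585 to 3.14 ± 2.00 FPKM (log2 4.89, SE 0.58, edgeR adjusted p = 0.00274). Ubd, a ubiquitin-like modifier, went from 2.26 ± 1.80 to 36.4 ± 20.3 FPKM, Alpi, an alkaline phosphatase, from 0.897 ± 0.984 to 17.0 ± 9.70 FPKM and Gbp2b from 0.030 ± 0.0294 to 1.4975 ± 1.5003 FPKM. The 8 largest falls were Bend7, Dynap, Muc5b, Kcnab1, Ildr2, Saa3, Pacsin1 and Mal2. Saa3, an acute phase protein, went from 19.6 ± 13.0 to 1.75 ± 0.786 FPKM (log2 -3.59, SE 0.63, edgeR adjusted p = 0.0146), Muc5b, a mucin, from 1.57 ± 1.19 to 0.110 ± 0.0698 FPKM and Mal2 from 14.7 ± 12.6 to 1.54 ± 0.443 FPKM. H2-Eb2 did not pass in edgeR without control replicate 3 (0.0558), Xcl1 without control replicate 2 (0.0523), Ceacam18 without sgADAR1 replicate 4 (0.0660), or Saa3 without sgADAR1 replicate 4 (0.0517). Bend7 did not pass without sgADAR1 replicate 1, 2 or 4 (0.0625, 0.0630 and 0.0881), Dynap without sgADAR1 replicate 1, 2 or 4 (0.0691, 0.0752 and 0.0890) or Ildr2 without sgADAR1 replicate 2, 3 or 4 (0.0594, 0.0689 and 0.0861). Mal2 did not pass without control replicate 3 (0.0540) or sgADAR1 replicate 2, 3 or 4 (0.0627, 0.0606 and 0.0776), and with 1 library left out Kcnab1 passed only without control replicate 4 (0.0517 to 0.147 otherwise).

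**Figure D3:**
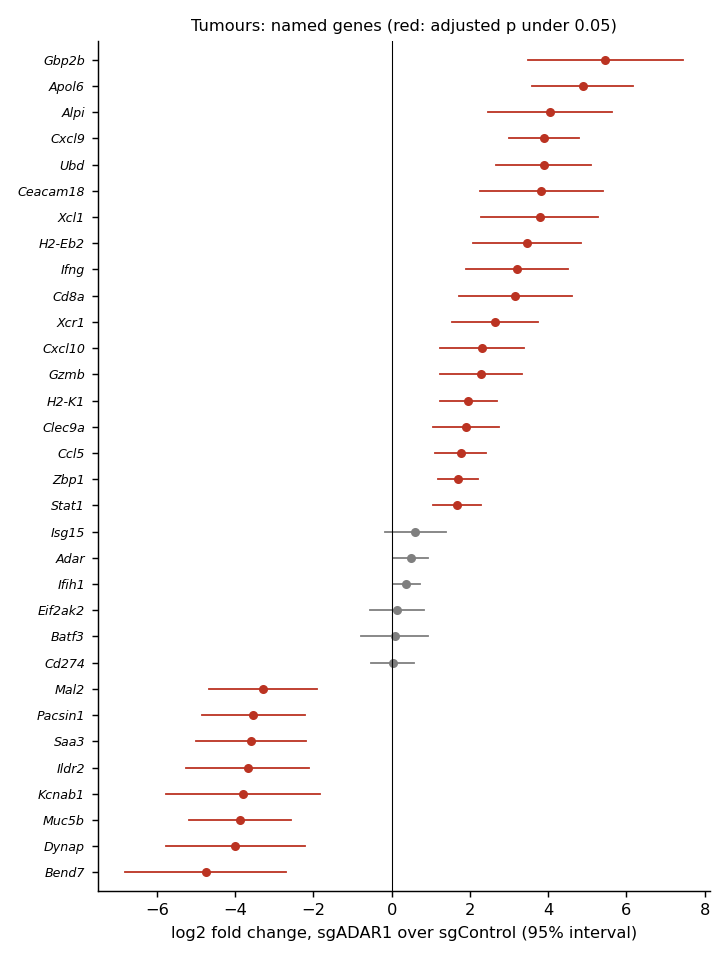
Log2 fold change in tumours, sgADAR1 over control (horizontal axis), of genes named by rule; points are edgeR estimates, lines 95% intervals, and red marks an adjusted p under 0.05 (n = 4 per group). Cxcl9 stood at 3.88 and Cd274 at 0.03.

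Other tumour lists called by camera were lost with an estimated correlation. JAK-STAT and interferon receptors held 1 higher and 0 lower of 16, also when adjusted over the list alone (1 and 0; median 0.15, camera adjusted p = 0.0242; adjusted p = 0.117 with an estimated correlation), and did not pass without control replicate 1 (0.0589). Necroptosis and pyroptosis genes held 1 higher and 0 lower of 14 (2 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 0.0214; adjusted p = 0.0989 with an estimated correlation), and did not pass without sgADAR1 replicate 1 or 4 (0.0572 and 0.0644). Regulatory T cell and exhaustion markers held 1 higher and 0 lower of 12, also over the list alone (1 and 0; median 0.38, camera adjusted p = 0.0214; adjusted p = 0.271 with an estimated correlation), and did not pass without control replicate 1 (0.0970) or sgADAR1 replicate 4 (0.0644). Type 2 conventional dendritic cell markers held 0 higher and 0 lower of 9 (2 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 0.0163; adjusted p = 0.345 with an estimated correlation), and did not pass without sgADAR1 replicate 3 (0.0830). Immediate early and heat shock genes held 0 higher and 1 lower of 15 (0 and 4 adjusted over the list alone, median -0.39, camera adjusted p = 0.000337; adjusted p = 0.0517 with an estimated correlation). Cholesterol synthesis genes held 0 called genes of 15 (0 also over the list alone, median -0.25, camera adjusted p = 0.0214; adjusted p = 0.621 with an estimated correlation), and did not pass without control replicate 2 (0.102) or sgADAR1 replicate 1 or 2 (0.226 and 0.235). Mitochondrially encoded genes held 0 called genes of 13 (0 also over the list alone, median -0.47, camera adjusted p = 0.0313; adjusted p = 0.645 with an estimated correlation), and did not pass without control replicate 2 or 3 (0.343 and 0.320) or sgADAR1 replicate 1 or 2 (0.132 and 0.171). Their share of counts was 13.1, 22.5, 23.3 and 7.33% in the control libraries and 9.92, 9.90, 16.2 and 14.5% in the sgADAR1 libraries.

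The remaining tumour lists did not pass by camera in the fit reported here. Values of other settings at which a list passed are given beside it. Counts here are higher and lower genes over all genes tested, then adjusted over the list alone. Epithelial and ductal markers held 0 and 0 of 14 (0 and 0 adjusted over the list alone), with a median of 0.03, a mean of -0.16 and a camera direction down (adjusted p = 0.561). Cell cycle genes held 0 and 0 of 29 (0 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.692; 0.00740 with limma array weights), and integrated stress response genes 1 and 0 of 24 (1 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.799). Apoptosis genes held 2 and 0 of 21 (3 and 2 adjusted over the list alone, median 0.11, camera adjusted p = 0.191; fry 0.0468) and p53 target genes 1 and 0 of 16 (1 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.236; fry 0.0209, limma with no filter 0.0181). NF-kB target genes held 0 and 1 of 21 (2 and 2 adjusted over the list alone, median -0.07 but 0.13 under another scaling, camera adjusted p = 0.236). MYC and ribosome biogenesis genes held 0 and 0 of 16 (0 and 0 adjusted over the list alone, median -0.10 but 0.10 under another scaling, camera adjusted p = 0.247). Hypoxia and glycolysis genes held 1 and 0 of 17 (1 and 0 adjusted over the list alone, median -0.33, camera adjusted p = 0.240), and passed without control replicate 4 (0.0394) and with limma array weights (0.0274). Epithelial-mesenchymal transition genes held 0 and 0 of 15 (0 and 0 adjusted over the list alone, median -0.22 but 0.03 under another scaling, camera adjusted p = 0.0700), and passed without control replicate 1 or 3 (0.0412 and 0.0345) or sgADAR1 replicate 2 or 4 (0.0335 and 0.0411) and, with all libraries, with no filter (0.0164), a block by replicate number (0.0389), DESeq2 (0.0373), limma (0.0447), a pseudocount of 0.1 (0.0479) and TPM (0.0496). Mature dendritic cell markers held 1 and 0 of 10 (1 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 0.236; fry 0.0468). Plasmacytoid dendritic cell markers held 1 and 1 of 4 (1 and 1 adjusted over the list alone), with a median of 0.17, a mean of -0.14 and a camera direction down (adjusted p = 0.866). B and plasma cell markers held 0 and 0 of 6 (2 and 0 adjusted over the list alone, median 1.30, camera adjusted p = 0.191), and passed without sgADAR1 replicate 2 (0.0364), with no filter (0.0138) and with DESeq2 (0.0219). Those fits all held sgADAR1 replicate 3, whose mean B cell level was 4.69 log2 CPM against 0.55 to 2.05 in the others. Mast cell and eosinophil markers held 0 and 0 of 7 (0 and 0 adjusted over the list alone, median 0.77, camera adjusted p = 0.219). The muscle, adipocyte, erythroid, keratinocyte and histone lists held 0 called genes, and adjusted over the list alone 1 keratinocyte marker was higher. Skeletal muscle markers (12 genes, median 0.53, camera adjusted p = 0.0935) passed without control replicate 4 (0.000490) or sgADAR1 replicate 1 (0.00360) and, with all libraries, with no filter (0.0358) and in limma with median-ratio rescaling (0.0309), quantile normalization (0.0413) and array weights (0.0160). Adipocyte markers (9 genes, median 0.28, camera adjusted p = 0.0959) passed without control replicate 1 or 4 (0.0135 and 0.0342), with no filter (0.0225) and with DESeq2 (0.0489). Erythroid markers (4 genes, median -0.26, camera adjusted p = 0.427) passed without sgADAR1 replicate 3 (0.0232). Keratinocyte markers (4 genes) had a median of -0.21, a mean of 0.14 and a camera direction up (adjusted p = 0.850), and replication-dependent histone genes (3 genes) a median of -0.35 (camera adjusted p = 0.297).

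Of 15995 genes tested in the tumours, 493 (3.08%) passed, 304 higher and 189 lower, and 390 of these changed at least 2-fold (250 higher, 140 lower; edgeR, Benjamini-Hochberg). Groups did not overlap for 9.87% of tested genes, where chance gives 2.86%. The count fell to 256 without control replicate 2, 220 without control replicate 3, 277 without sgADAR1 replicate 2, 294 without sgADAR1 replicate 3 and 194 without sgADAR1 replicate 4. Across lists, camera called 22 of 42, 17 higher and 5 lower, and 8 with an estimated correlation. Other splits of the same libraries, some of which still hold part of the real difference, called up to 26 lists at the preset correlation. The number of lists called thus does not set the real grouping apart. With FPKM rescaled to TPM in limma, which put the median log2 fold change of all genes at 0.15 against -0.01 here, 187 genes were higher and 35 lower. With array weights, at a median of 0.12, 575 were higher and 178 lower, with a pseudocount of 0.1, at 0.10, 207 and 54, and with limma on FPKM alone 214 and 57. On the first principal component libraries numbered 1 and 2 lay below those numbered 3 and 4 within each group. Chi-square per degree of freedom between libraries followed that division in the sgADAR1 group (26.4 for 1 and 2 and 11.96 for 3 and 4, against 49.3 to 59.9 for the other pairs). It did not in the controls (48.5 for 1 and 2 and 99.8 for 3 and 4, against 34.1 for 2 and 3). With that division as a block, chosen after seeing the data, 838 genes passed.

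**Figure D4:**
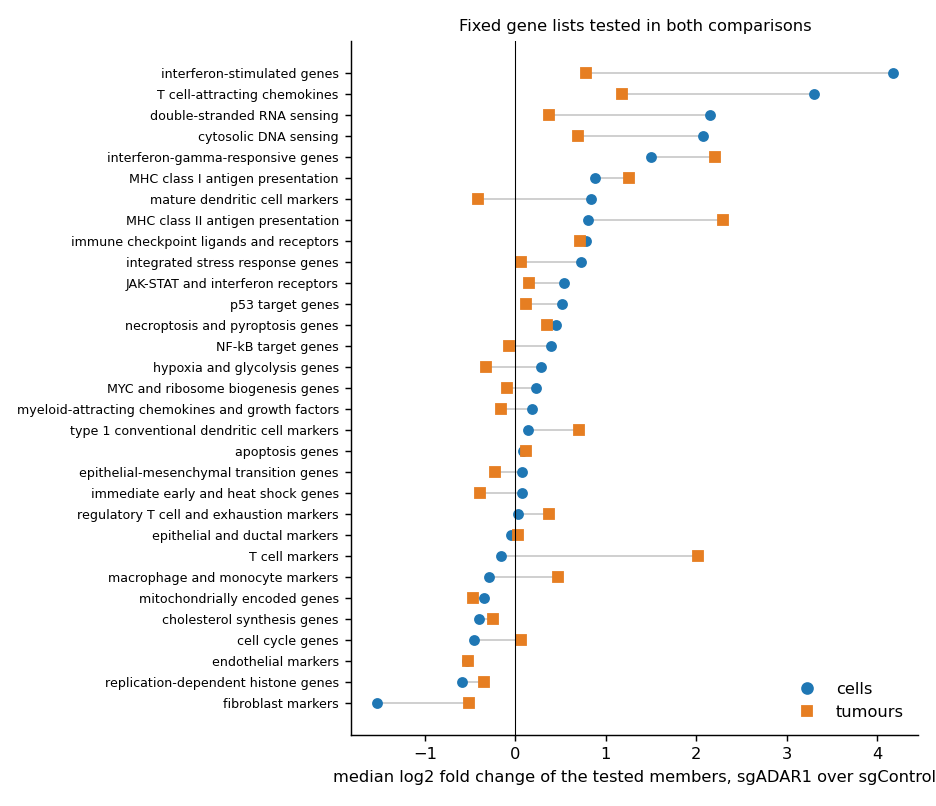
Median log2 fold change, sgADAR1 over control (horizontal axis), of the measured members of the 31 lists tested in both comparisons; circles are cells and squares tumours. Interferon-stimulated genes had medians of 4.17 and 0.78, and interferon-gamma-responsive genes 1.49 and 2.20; medians near 0 took the other sign under another scaling, in cells for the apoptosis, epithelial-mesenchymal, immediate early, regulatory T cell and type 1 dendritic cell lists and in tumours for the epithelial-mesenchymal, MYC, myeloid chemokine and NF-kB lists.

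The last comparison asks which changes cells and tumours had in common and where their fold changes differed. Of 13771 genes tested in both, 127 were higher in both where 37.7 were expected (Fisher's exact p = 3.60e-44) and 88 were lower in both where 29.4 were expected (Fisher's exact p = 2.43e-25). Another 32 passed in opposite directions. Fisher's test treats genes as independent, which they are not, so its p-values do not measure replication across libraries. Under other settings the genes higher and lower in both numbered 93 and 25 with limma on FPKM, 89 and 13 with TPM, 96 and 42 with median-ratio rescaling, 229 and 89 with array weights and 60 and 15 with a mean FPKM of at least 5. The sum of 215 shared genes became 124 without tumour control replicate 2, 108 without tumour control replicate 3, 136 without tumour sgADAR1 replicate 2, 118 without tumour sgADAR1 replicate 3 and 97 without tumour sgADAR1 replicate 4. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.290 and a Spearman rho of 0.189. A test of the difference itself, adjusted by Benjamini-Hochberg, was passed by 1967 genes. Of these, 1317 had estimates of opposite sign, counted whether or not the gene passed in either comparison. Rsad2, for example, had 9.98 in the cells and -0.08 in the tumours, so this count does not mean opposite regulation. The larger value was in the cells for 1057 genes and in the tumours for 910. Which side held more depended on the setting. With the larger value in the cells and in the tumours there were 444 and 1297 with limma on FPKM, 260 and 642 with TPM, and 602 and 2638 with array weights. There were 875 and 931 with no filter and 887 and 544 with median-ratio rescaling. Among 14 named genes in both comparisons, 12 differed, 9 with the larger rise in the cells and 3 in the tumours. The cell minus tumour difference in log2 fold change was 5.63 for Cmpk2, 4.28 for Isg15, 2.69 for Cd274, 2.52 for Ifih1, 2.52 for Cxcl10 and 2.03 for Eif2ak2. It was -1.20 for H2-K1, -1.16 for Tap1 and -1.004 for Stat1. For Cxcl9 it was -1.15 and for Ido1 -0.42, and neither passed (adjusted p = 0.0939 and 0.763 by the moderated standard errors of edgeR). Cell and tumour libraries differed in culture, in interferon gamma and in the cells they held, so the difference cannot be assigned to any 1 of these.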

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

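The tests of library scaling, of exchanged libraries, of fibroblasts in the cultures, of cancer cell share and of lymphoid tissue were chosen only after the result was seen, and the others before it.

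Adar counts were higher, not lower, in the cell libraries labelled sgADAR1. Scaling was argued against, since the smallest log2 fold change over the scaling alternatives was 1.25. Single libraries exchanged between the groups were argued against, since 0 libraries had an interferon-stimulated-gene level inside the range of the other group (3.28 to 3.48 log2 CPM in controls, 7.83 to 7.99 in sgADAR1). Whether the transcript followed the interferon response cannot be told apart from a direct effect of the guide: within groups the correlation over 14 libraries was r = -0.18 (permutation p = 0.640) and rho = -0.17 (permutation p = 0.613), and r = -0.15 without the 2 libraries farthest from the median, while in the cells both levels were higher in the sgADAR1 group. This correlation leaves out the difference between groups, where Adar rose in the cells, so it cannot decide the question. A response of the Adar gene to interferon, a transcript left in place by the guide and an exchange of whole groups stay open, and the last was not tested.

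A set of 26 genes, among them Fgfr1, Col3a1 and Sparc, with control levels of 1.11 to 23.7 FPKM had log2 fold changes below -4 in the cell libraries labelled sgADAR1. Fibroblasts mixed into the control cultures were argued against, since the highest mean FPKM of Col1a2, Dcn and Lum, abundant in fibroblasts, was 0.00333 in the controls. Loss of large chromosome segments at most of these genes, which lie on 12 chromosomes, was argued against. The 249 tested neighbours within 500 kb, leaving out the 26 genes themselves, had a median log2 fold change of -0.12. Of these neighbours 6.43% were more than 2-fold lower against 6.09% of all genes tested. Loss at single places was not excluded, since Obsl1 and Inha, both in the set, lie side by side on chromosome 1 (log2 -4.27 and -6.07). Differences between the cell populations that carry each guide, apart from the edit itself, may also account for the pattern and were not tested. A loss of ADAR1 is the biological explanation that the design names, and these libraries do not part it from such differences.

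T cell and antigen presentation genes were higher in the tumour libraries labelled sgADAR1. A lower share of cancer cells was argued against as the whole cause, since it would raise the markers of every other cell type alike. The T cell level rose by log2 2.21 relative to the endothelial level (exact p = 0.0286, the smallest possible). A lower share as part of the cause was not excluded. In the same family of 5 comparisons the T cell level rose by 2.04 relative to fibroblasts, 1.92 relative to epithelial cells and 2.68 relative to neutrophils, and class II genes by 1.70 relative to macrophages (each exact p = 0.0286, Benjamini-Hochberg adjusted p = 0.0286). The T cell and class II lists had already been called higher in these libraries, so these p-values add no separate support. Lymphoid tissue in sgADAR1 replicate 3, whose B cell level was 4.69, was argued against as the whole cause, since without that library the T cell list had a median of 1.73 (camera adjusted p = 9.63e-20). More T cells, or more active ones, in tumours labelled sgADAR1 may explain the pattern, a hypothesis found on the same data, and the site and size of the tumours stay open. The division of libraries numbered 1 and 2 from those numbered 3 and 4 was argued against as the cause. Both groups lie on each side in equal number. With that division as a block, chosen after seeing the data, 490 of the 493 genes still passed. The labels do not say what that division stands for.

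Other divisions of the same libraries were fitted. For genes in the cells 10 splits are too few for a share under 0.05: the real split gave 5180 genes (1 of 10 as large) and the highest other 0 by edgeR, with 45 to 388 genes at an unadjusted p under 0.05 and 0 by limma on FPKM. The 3 other splits that also part all 3 numbered pairs gave 0 genes by edgeR, with 49, 70 and 94 at an unadjusted p under 0.05 and 0 by limma. For lists in the cells, where 10 splits are again too few, the real split gave 21 (1 of 10 as large) and the highest other 18. For genes in the tumours chance was argued against for the count by edgeR adjusted p, but not excluded. The real split gave 493 genes (1 of 35 as large, the smallest share possible) and the highest other 61. At an unadjusted p under 0.05 chance was not argued against, since the real split gave 2334 genes and 2 others gave 3149 and 2618. The split with 61 set replicates 1 and 2 of both groups against replicates 3 and 4, with 53 genes by limma on FPKM, which points to a structure of the samples, which chi-square per degree of freedom between libraries followed in the sgADAR1 group (26.4 for 1 and 2 and 11.96 for 3 and 4, against 49.3 to 59.9 for the other pairs) but not in the controls (48.5 and 99.8, against 34.1 for 2 and 3). With that division as a block the real comparison gave 838 genes. For lists in the tumours chance was not excluded, since 4 of 35 splits gave at least the real 22 and the highest other gave 26. For genes shared by cells and tumours the real pair of splits gave 215 (1 of 100 pairs as large) and the highest other 13, but the other cell splits called 0 genes, so that of the 100 pairs the 10 with the real cell split were the ones that could share any, too few for a share under 0.05. For genes whose fold change differed the count does not decide: 5 of 100 pairs of splits gave at least the real 1967 and the highest other gave 3577, but the 4 others held the real cell split and so the real cell difference. Pairs without the real cell split gave at most 30.

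In 15 of 140 tests within a tumour group of 4 libraries, 1 library lay far from the others, each time for a named gene. The tests covered named genes, total counts and the mitochondrial share. Chance gives about 1 in 20 for independent, normally distributed values, which FPKM values of related genes need not be. Control replicate 4 was apart for Clec9a (0.70 FPKM, the others 0.21 to 0.28), Sp100 (2.54, the others 1.12 to 1.22), C1qc (49.2, the others 33.7 to 35.1) and Cd86 (2.49, the others 1.76 to 1.84). Control replicate 1 was apart for Isg15 (20.2, the others 7.40 to 8.83), Ubd (4.92, the others 1.10 to 1.75) and H2-Aa (42.8, the others 27.7 to 28.3). Control replicate 2 was apart for Bend7 (3.27, the others 0.41 to 0.57) and Ildr2 (3.50, the others 0.52 to 0.78). Replicate 4 of sgADAR1 was apart for Cxcl9 (149, the others 60.5 to 66.2), Xcl1 (13.7, the others 2.51 to 3.88) and Gbp2b (3.73, the others 0.51 to 0.97). Replicate 1 of sgADAR1 was apart for Adar (4.99, the others 7.38 to 7.84), replicate 2 for Alpi (31.4, the others 11 to 13.5) and replicate 3 for Ccl5 (7.50, the others 11.02 to 11.5).

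The fold change differed between cells and tumours, by a test of the difference, for 1967 genes. Among named genes the cell minus tumour difference in log2 was 5.63 for Cmpk2, 4.28 for Isg15, 2.69 for Cd274, 2.52 for Ifih1, 2.52 for Cxcl10, 2.03 for Eif2ak2, 1.53 for Ccl5, 1.45 for Zbp1 and 0.98 for Adar. It was -1.20 for H2-K1, -1.16 for Tap1 and -1.004 for Stat1. The adjusted p of these 12 differences ran from 2.15e-09 for Cmpk2 to 0.0380 for Stat1, from the standard errors of the edgeR fits.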

How the results depend on the processing

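Leaving out mitochondrial and ribosomal RNA genes, leaving out both cell libraries numbered 1, and a block of tumour libraries numbered 1 and 2 against 3 and 4 were chosen after seeing the data, and the other alternatives before. Where a value below moved, the cause was not tested unless fewer genes or libraries show it. In the cells every named gene kept its direction and its side of the threshold, in 708 values under other settings, 336 with 1 library left out and 56 without both libraries numbered 1, and Adar stayed between 1.14 and 1.54. Many of these genes were chosen from the same data for a large fold or a small p, so they do not stand for all calls. Cell gene counts within 1.5 times of 5180 were 5182 with DESeq2-type size factors, 5775 with no filter, 6620 with a block by replicate number, 4961 with DESeq2, 4945 with limma, 4903 with a pseudocount of 0.1, 3938 with limma and no filter, 4235 with median-ratio rescaling, 4473 with quantile normalization, 4347 with TPM, 6801 with array weights, 3647 to 6028 with 1 library left out, 5172 without mitochondrial and ribosomal RNA genes and 6792 without both libraries numbered 1. The count was 1374 with at least a 2-fold change and 3062 with a mean FPKM of at least 5, which tests fewer genes. A like count did not mean the same genes. Of the 5180, the limma fits on FPKM, which filter genes otherwise, called 3240 (no filter) to 4030 (median-ratio rescaling). DESeq2 called 4735 of them and edgeR with DESeq2-type size factors 5156. In the tumours 680 gene values kept direction and side under other settings, 125 lost the threshold, 14 gained it and 2 turned. With 1 library left out 398 kept both, 130 lost it, 3 gained it and 5 turned, and 29 of 60 named calls held in all 8 fits. For lists, 365 values in cells and 576 in tumours kept both under other settings, 58 and 34 lost the call, 10 and 27 gained it, and 13 and 23 turned. With 1 library left out 169 and 289 kept both, 8 and 13 lost it, 5 and 15 gained it and 4 and 19 turned, and without both cell libraries numbered 1, 27 kept both, 3 lost it and 1 gained it. Depth limits genes with 0 to 3 counts in a group, whose fold rests on counting error. In simulated data, with genes drawn independently, 38.5% of 2-fold changes were found at tumour spread. Smaller tumour changes may therefore mostly have been missed here, although the simulated rate need not hold for these data.

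With an estimated correlation camera called 7 lists in cells and 8 in tumours, and fry called 25 and 19. With limma on FPKM camera called 16 and 22, and with a mean FPKM of at least 5, 14 and 16. The tumour gene count was 181 with a mean FPKM of at least 5, 1087 with DESeq2, 271 with limma, 261 with a pseudocount of 0.1, 133 with limma and no filter, 317 with median-ratio rescaling, 307 with quantile normalization, 222 with TPM, 753 with array weights, 838 with the block of numbers 1 and 2 against 3 and 4, 497 with DESeq2-type size factors, 596 with no filter and 492 without mitochondrial and ribosomal RNA genes. Tumour Adar passed with array weights only (log2 0.63, limma adjusted p = 0.0482). Shared genes numbered 75 with a mean FPKM of at least 5, 118 with limma, 114 with a pseudocount of 0.1, 60 with limma and no filter, 138 with median-ratio rescaling, 135 with quantile normalization and 102 with TPM. Genes whose fold change differed numbered 957 with a mean FPKM of at least 5, 902 with TPM and 3240 with array weights.

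Lists that turned did not pass before or after, by camera adjusted p. In cells epithelial markers turned at 0.897 with limma, 0.869 with a pseudocount of 0.1, 0.963 with limma and no filter, 0.917 with median-ratio rescaling, 0.697 with quantile normalization, 0.851 with TPM and 0.867 with array weights. Cell epithelial-mesenchymal genes turned at 0.915 with limma, 0.869 with a pseudocount of 0.1 and 0.980 with TPM, regulatory T cell markers at 0.975 with no filter and 0.776 with limma and no filter, and T cell markers at 0.729 with limma and no filter. In tumours plasmacytoid dendritic cell markers turned at 0.236 with no filter, 0.363 with DESeq2, 0.185 with limma, 0.149 with a pseudocount of 0.1, 0.335 with limma and no filter, 0.197 with median-ratio rescaling, 0.304 with quantile normalization, 0.0704 with TPM, 0.311 with array weights and 0.693 without mitochondrial and ribosomal RNA genes. Keratinocyte markers turned at 0.409 with no filter, 0.595 with DESeq2, 0.214 with limma, 0.232 with a pseudocount of 0.1, 0.554 with limma and no filter, 0.219 with median-ratio rescaling, 0.232 with quantile normalization, 0.265 with TPM and 0.0730 with array weights. Integrated stress response genes and epithelial markers turned at 0.959 with a mean FPKM of at least 5, and MYC genes at 0.931 with array weights. Batf3 was -0.046 with quantile normalization.

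With replicate number as a block the cells gave 6620 genes, 3382 higher and 3238 lower, and 21 lists. In the tumours the numbers do not pair the libraries, since the same numbers correlated at 0.48, -0.18, 0.16 and 0.03 in deviations from the group mean. That block gave 373 genes there, 246 higher and 127 lower, 23 lists, 0.49 for Adar, -0.018 for Batf3 and a turn of integrated stress response genes at 0.972.

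With 1 library left out the tumour gene count ran from 194 to 515 and the shared count from 97 to 232. Log2 fold changes in tumours ran from -0.048 to 0.37 for Eif2ak2, from -0.28 to 0.29 for Batf3 and from -0.16 to 0.23 for Cd274. Adjusted p by camera ran in cells from 0.670 to 0.982 for epithelial markers and from 0.544 to 0.992 for regulatory T cell markers. In tumours it ran from 0.306 to 0.974 for integrated stress response genes, from 0.0804 to 0.943 for cell cycle genes, from 0.0394 to 0.839 for hypoxia genes, from 0.437 to 0.957 for plasmacytoid dendritic cell markers, from 0.0364 to 0.786 for B cell markers and from 0.499 to 0.943 for keratinocyte markers.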

Other observations

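The gene ontology tests were chosen only after the results of the fixed lists were seen, and the lists before. In the cells, genes of cell death and inflammation were partly higher in the libraries labelled sgADAR1. Of 21 apoptosis genes, 6 rose and 2 fell, as they did adjusted over the list alone (6 and 2; camera adjusted p = 0.00626; adjusted p = 0.144 with an estimated correlation), with a median of 0.09 that was -0.08 under another scaling. The limma fits on FPKM did not call this list, at camera adjusted p from 0.158 to 0.363. Tnfsf10, a death receptor ligand, went from 0.407 ± 0.0404 to 18.1 ± 1.31 FPKM, the executioner caspase Casp7 from 4.20 ± 0.147 to 9.09 ± 0.841 FPKM and Bid from 13.0 ± 0.408 to 20.1 ± 1.40 FPKM. Of 12 necroptosis and pyroptosis genes, 6 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.45, camera adjusted p = 0.00138; adjusted p = 0.0845 with an estimated correlation). Mlkl, the pore-forming protein of necroptosis, went from 42.8 ± 1.58 to 94.8 ± 3.65 FPKM, and Aim2, a sensor of cytosolic DNA, from 12.2 ± 0.270 to 4.94 ± 0.333 FPKM. Of 20 NF-kB target genes, 11 rose and 2 fell (11 and 4 adjusted over the list alone, median 0.40, camera adjusted p = 0.00796; adjusted p = 0.434 with an estimated correlation). Il6 went from 0.353 ± 0.0551 to 2.81 ± 0.531 FPKM, Il1a from 3.27 ± 0.613 to 10.0 ± 1.08 FPKM and Sod2 from 9.66 ± 0.650 to 16.8 ± 1.41 FPKM. Of 14 myeloid-attracting chemokines and growth factors, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0131; adjusted p = 0.419 with an estimated correlation), and the list did not pass without control replicate 1 (0.0553). Epithelial-mesenchymal transition genes went both ways, 5 higher and 5 lower of 15 (5 and 5 adjusted over the list alone), with a median of 0.08 that was -0.06 under another scaling, a mean of -0.86 and a camera direction down (adjusted p = 0.0699), and passed without control replicate 1 (0.0235), with no filter (0.0278) and with fry (0.0173). Sparc, a matrix glycoprotein, went from 23.7 ± 1.92 to 0.973 ± 0.147 FPKM (log2 -4.44) and Snai1, a transcription factor of this transition, from 2.39 ± 0.512 to 0.133 ± 0.0814 FPKM. Tgfbi had 129 counts against 1, a ratio of 108 (19.1 to 4304). By ontology, genes at least 2-fold higher held 55 of 144 for defense response to virus where 5.19 were expected (hypergeometric BH adjusted p = 2.29e-39), and genes at least 2-fold lower held 23 of 90 for extracellular matrix organization where 5.07 were expected (BH adjusted p = 6.67e-07).

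In the tumours, macrophage and monocyte markers held 4 higher and 0 lower of 18 (4 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 0.000133; adjusted p = 0.234 with an estimated correlation). The complement genes C1qb and C1qc went from 74.0 ± 15.3 to 135 ± 14.9 and from 37.9 ± 7.56 to 68.3 ± 9.04 FPKM, and Trem2, a lipid receptor of macrophages, from 1.57 ± 0.478 to 3.25 ± 0.461 FPKM. C1qb did not pass in edgeR without sgADAR1 replicate 4 (0.0579), C1qc without control replicate 2 or 3 (0.0510 and 0.0651) or sgADAR1 replicate 4 (0.0708), and with 1 library left out Trem2 passed only without control replicate 4 or sgADAR1 replicate 2 (0.0665 to 0.108 otherwise). Of 16 immune checkpoint genes, 2 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.71, camera adjusted p = 0.000200; adjusted p = 0.0989 with an estimated correlation). These were the receptor Pdcd1, from 0.487 ± 0.259 to 3.13 ± 1.44 FPKM, and the costimulatory ligand Cd86, from 1.98 ± 0.345 to 3.97 ± 0.678 FPKM. With 1 library left out Pdcd1 passed only without control replicate 1 or sgADAR1 replicate 3 (0.0503 to 0.0926 otherwise) and Cd86 only without control replicate 4 or sgADAR1 replicate 2 (0.0556 to 0.104 otherwise). Ido1 had 0.968 ± 0.746 and 6.598 ± 3.39 FPKM (edgeR adjusted p = 0.0708) and passed without control replicate 1 or 4 (0.0484 and 0.0430), and Cd274 had 5.16 ± 2.12 and 5.53 ± 1.52 FPKM (edgeR adjusted p = 0.980). Of 15 myeloid-attracting chemokines and growth factors, 1 rose and 2 fell (2 and 6 adjusted over the list alone), with a median of -0.16 that was 0.14 under another scaling, and the list (camera adjusted p = 0.0986) passed without control replicate 1 (0.000865), with no filter (0.0446) and with DESeq2 (0.0356). The neutrophil attractants Cxcl2 and Cxcl3 went from 23.9 ± 16.9 to 3.09 ± 0.845 and from 5.83 ± 3.21 to 1.73 ± 0.228 FPKM, and Flt3l, a growth factor of dendritic cells, from 0.655 ± 0.101 to 2.10 ± 0.901 FPKM. Cxcl2 did not pass in edgeR without control replicate 2 (0.0510) or sgADAR1 replicate 2 or 4 (0.0604 and 0.0762), and with 1 library left out Cxcl3 passed only without control replicate 1 (0.0567 to 0.101 otherwise) and Flt3l only without sgADAR1 replicate 1 (0.0569 to 0.118 otherwise). By ontology, genes at least 2-fold higher held 15 of 30 for defense response to protozoan where 0.471 were expected (hypergeometric BH adjusted p = 8.98e-17) and 9 of 18 for presentation of exogenous peptide on MHC class II where 0.283 were expected (BH adjusted p = 3.60e-10). Genes at least 2-fold lower held 9 of 119 for extracellular matrix organization where 1.11 were expected (BH adjusted p = 0.00216).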
